A study of Mus musculus with 4 samples.

How the data were processed

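Peak lists of 4 ChIP-exo libraries of D3 mouse embryonic stem cells were analysed, 1 each for endogenous Sox2, Halo-Sox2, Halo-Sox2M and Halo-Sox2D. Per the labels' protocols, nuclei were sonicated, the lysates cleared, and protein-DNA complexes isolated with an antibody against Sox2 or on HaloLink resin, before libraries were made by a published ChIP-exo procedure. Per the submitters' processing notes, Bowtie2 and the mm10 build were used. The version of Bowtie2, the peak caller, its threshold, the handling of reads that map to several places and the read filters are not given in the sources used here. The authors deposited 1 list per library, each a set of chromosome, start and end coordinates with no score, height or read number. A list therefore records where peaks were called and not how strong they were, and its length depends on depth and threshold as well as on binding. No input or resin-only library was used here.

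Each library was taken as its own group from the labels. With 1 library per group no model was fitted and no test between conditions was run. Shares carry 95% Wilson intervals (scipy 1.17.1) over peaks, sites or genes, and ratios of peak numbers carry exact binomial intervals. Both cover counting error only. The main comparisons were endogenous Sox2 with Halo-Sox2, Halo-Sox2 with Halo-Sox2M, and Halo-Sox2 with Halo-Sox2D. Peaks were called shared at an overlap of at least 1 bp, computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 and checked against bedtools 2.31.1, which gave the same number for each ordered pair of libraries. The chance level was described by 100 circular shifts of one list within its chromosomes, and by 100 moves of one list by 1 to 10 kb in either direction, which keep it in the same neighbourhood. The local moves were added after the data were seen. For sites, peaks whose centres lay within 500 bp were joined.

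Gene positions came from a RefSeq table of GRCm38.p6, whose primary chromosomes have the coordinates of mm10, with 21887 protein-coding genes among 49943 genes on the chromosomes used. The table gives starts and ends of genes without strand. The planned distances to transcription start sites were therefore replaced by distances to the gene body (within 50 kb) and by the share of peaks within 1 kb of either end of a protein-coding gene. Peaks on mitochondrial DNA and unplaced sequence were left out of that share, which was compared with 100 uniform placements on the same chromosomes. Exons and introns were not told apart. The fixed gene lists covered pluripotency (40 genes), signalling (30), neural (30), mesendoderm (20), trophoblast (14), fibroblast (20), housekeeping (20), other tissues (20) and chromatin regulators (30). All 224 symbols matched the table. For each list the number of genes with a peak was set beside 10000 random lists of as many protein-coding genes, matched on quintiles of the number of neighbouring genes and, because windows ran over gene bodies, also on quintiles of gene length. Percentiles among random lists describe these libraries and are not tests of a condition.

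The libraries compared, the gene lists, the random lists (apart from gene length) and the rule for naming genes were fixed before the data were examined. The rule was: Sox2, Pou5f1 and Nanog in every library; for each main pair up to 10 list genes with an overlapping peak in both libraries, ordered by the summed number of peaks, up to 10 with peaks in the first library alone and up to 10 in the second alone, with ties in alphabetical order; and for each library the 5 protein-coding genes with most peaks. Other genes were named after their values were seen: Klf2, Rif1 and Foxd3 in the Halo-Sox2M count of pluripotency genes, Zfp42 in the Halo-Sox2D count, and genes in the closing section. Some genes that met the rule are not reported here.

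A set of peaks outside dense bins was defined after the data were seen, because some regions held very many peaks. It leaves out mitochondrial DNA, unplaced sequence and 11 bins of 100 kb with 15 or more peaks in any library. Lists were also thinned at random to the shortest list in 100 draws, to 1711 peaks over the whole genome and, added later, to 954 outside dense bins. The Halo-Sox2M list stayed whole in this. Random thinning need not keep the peaks that fewer reads or a stricter threshold would leave. The other alternatives were merged peaks, autosomes and X alone, reciprocal overlap of 50%, centres within 50 or 500 bp, gene windows of 20 and 100 kb or the nearest gene, and gene ends within 2 or 5 kb or of all annotated genes. A stricter peak threshold was not run because the lists hold no score. Motif shares and distances were planned and not run, since no genome sequence was used here.

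The code was tested on simulated data. With 500 peaks planted in lists as long as the real ones, 502 overlaps were recovered for endogenous Sox2 and Halo-Sox2 (7153 peaks), 501 for Halo-Sox2 and Halo-Sox2M (6558 peaks) and 501 for Halo-Sox2 and Halo-Sox2D (6558 peaks). With 30 list genes given a peak, 33, 34, 31 and 36 had one in simulated lists as long as those of endogenous Sox2, Halo-Sox2, Halo-Sox2M and Halo-Sox2D. With 20% of peaks planted at gene ends, 22.5% of the simulated endogenous Sox2 peaks were found there, on a background of 3.18%. Figures were drawn with matplotlib 3.10.9.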

Results

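ChIP-exo, in which an exonuclease trims immunoprecipitated DNA up to the crosslinked protein so that binding is placed finely, was used to map Sox2 in D3 mouse embryonic stem cells. Sox2 is an HMG-box transcription factor that acts with Oct4, the product of Pou5f1, to hold these cells in the pluripotent state. There were 4 libraries with 1 library in each group, so no difference between groups had a replicate check and no p-value was computed. Endogenous Sox2 was isolated with an antibody, and 3 fusions to HaloTag, a protein tag that binds covalently to a resin, were isolated on HaloLink resin. The fusions were Halo-Sox2, Halo-Sox2M with the changes labelled M47G, F50 and M51G (no replacing residue is given for F50), and Halo-Sox2D, which keeps Sox2 residues 1 to 120. The lists held 7153 peaks for endogenous Sox2, 6558 for Halo-Sox2, 1711 for Halo-Sox2M and 13833 for Halo-Sox2D. The median peak width was 11 bp in each library, within a range of 1 to 20 bp. Read depth is unknown because the lists carry neither read numbers nor scores, so the length of a list cannot be separated from sequencing depth or calling threshold. All intervals are 95% Wilson intervals over peaks, sites or genes that cover counting error only, and neighbouring peaks are not independent. A gene was counted as having a peak when a peak centre lay in its body or within 50 kb of it, and windows of neighbouring genes overlap.

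The genes of the core pluripotency factors, Sox2, Pou5f1 and Nanog, had peaks in the endogenous Sox2, Halo-Sox2 and Halo-Sox2D libraries, and Halo-Sox2M had a peak at Sox2 alone among these genes. At Pou5f1 (mm10 chromosome 17, 35506032 to 35510777) there were 10 endogenous Sox2 peaks, 3 Halo-Sox2 peaks, 7 Halo-Sox2D peaks and 0 Halo-Sox2M peaks. An endogenous Sox2 peak at 35505161 to 35505171, a Halo-Sox2 peak at 35505163 to 35505182 and a Halo-Sox2D peak at 35505157 to 35505164 met at one place, 0.86 to 0.872 kb below the lower end of the gene. At Nanog (chromosome 6, 122707489 to 122714633) the endogenous Sox2 peak at 122707411 to 122707422 overlapped the Halo-Sox2 peak at 122707402 to 122707420, less than 0.1 kb below the gene. The 5 Halo-Sox2D peaks at Nanog lay elsewhere, the nearest 1.469 kb below the gene. At the Sox2 gene itself (chromosome 3, 34649995 to 34652461), peaks of endogenous Sox2 (34653977 to 34653991 and 34654016 to 34654020), Halo-Sox2M (34654028 to 34654036) and Halo-Sox2D (34654001 to 34654002 and 34654034 to 34654052) lay together, 1.52 to 1.58 kb above the upper end of the gene. Halo-Sox2 had no peak at that place, and its 3 peaks lay inside the gene at 34650017 to 34650029 and 16.1 and 16.2 kb above it.

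**Figure D1:**
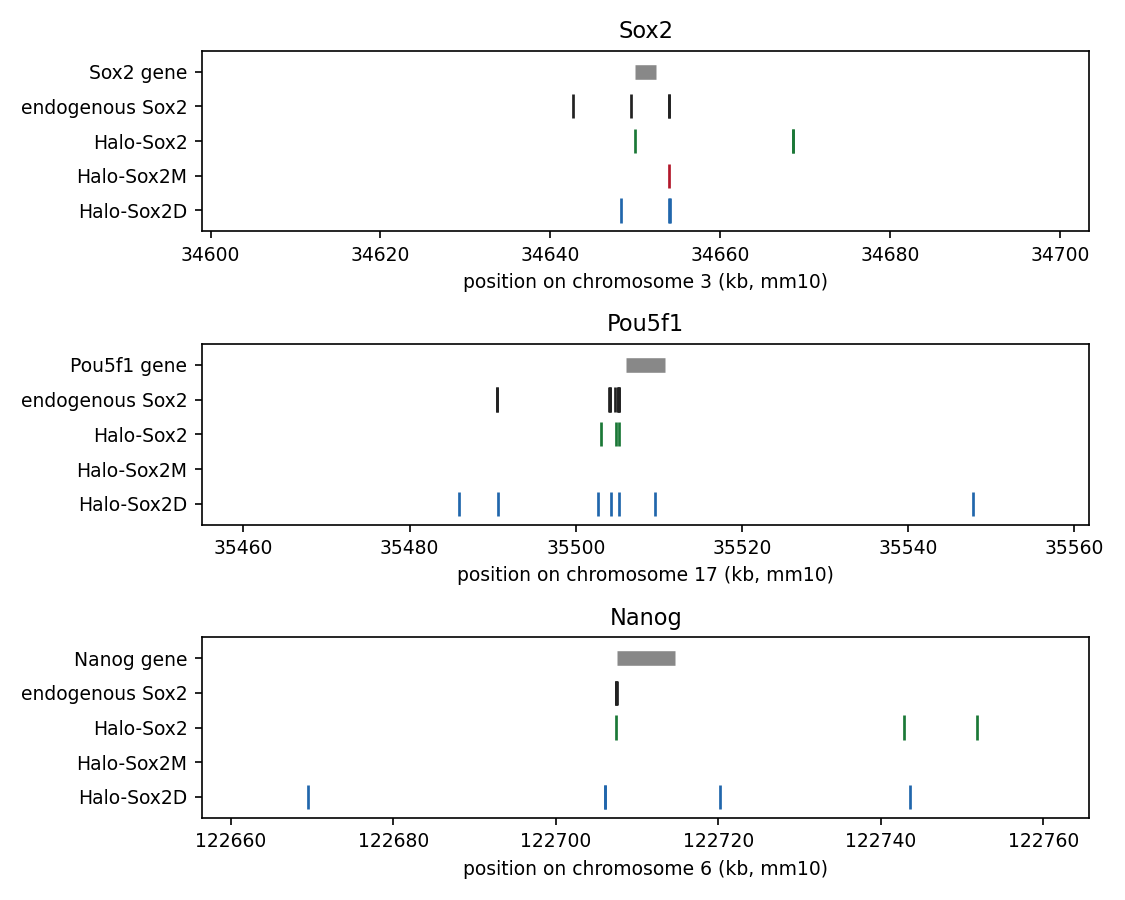
Peak positions in the 4 libraries (rows, one vertical line per peak, drawn wider than the peaks are) along the Sox2, Pou5f1 and Nanog genes (grey bars), with the position in kb in mm10 on the horizontal axis. Endogenous Sox2 and Halo-Sox2 peaks meet just below Pou5f1 and Nanog, and Halo-Sox2M has 1 peak at Sox2 and 0 at the other genes.

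The first comparison asked whether tagged Sox2 was found where the endogenous protein was. Peaks of both libraries gathered at pluripotency genes: 35 of the 40 genes of that list had an endogenous Sox2 peak and 28 had a Halo-Sox2 peak, against means of 9.25 and 10.5 in 10000 random lists of genes matched on gene density and length. Every random list held fewer in either library. Of the signalling genes, most of them of the LIF, FGF, BMP, Wnt and Nodal pathways, 18 and 19 of 30 had a peak, against random means of 8.20 and 9.29, again above all random lists. The genes with most peaks among those where peaks of both libraries overlapped were Spry2, an antagonist of FGF signalling (17 endogenous Sox2 and 11 Halo-Sox2 peaks), Esrrb, an orphan nuclear receptor of naive pluripotency (13 and 2), and Pou5f1. They were followed by Mtf2, a Polycomb-associated factor (8 and 3), Phc1 (7 and 4), Sall1 (9 and 2), Tcf7l1, a repressor in the Wnt pathway (6 and 5), the neighbouring Nodal antagonists Lefty1 and Lefty2 (7 and 2 at each) and Rax (6 and 2). The overlapping endogenous Sox2 peaks lay inside Esrrb (chromosome 12, 86471084 to 86471098), Mtf2 (chromosome 5, 108077193 to 108077205) and Tcf7l1 (chromosome 6, 72770363 to 72770374). Those at Phc1 lay 0.419 and 0.466 kb above the gene, and the pair counted for both Lefty genes lay 4.27 and 4.28 kb below Lefty2. In all, 21 of the 224 list genes had overlapping peaks of both libraries.

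Other list genes had peaks in one of these libraries and none in the other. There were 36 with endogenous Sox2 peaks alone, led by Smad7, an inhibitor of TGF-beta signalling, with 6 peaks, and Zfp281 with 5. Otx2, Tfap2c and Tfcp2l1 had 4 each, Dppa3, Gdf3 and Sox11 had 3 each, and Fn1 and Gata3 had 2 each. Another 29 had Halo-Sox2 peaks alone: Sox21, a neural SoxB gene, had 6, Tbx3 and Wnt3 had 3, Eomes and Sox1 had 2, and Actb, B2m, Dcn and Dnmt3l had 1. Among lineage genes, 13 of 30 neural genes had an endogenous Sox2 peak and 11 had a Halo-Sox2 peak, against random means of 5.46 and 6.01. The trophoblast list had 9 and 4 of 14 genes (random means 3.26 and 3.71), and the chromatin regulators had 17 and 16 of 30 (9.63 and 11.5). Mesendoderm genes had 2 and 6 of 20 (4.43 and 4.97), fibroblast genes 4 and 4 of 20 (5.06 and 5.84), housekeeping genes 8 and 9 of 20 (5.06 and 6.14) and genes of other tissues 3 and 5 of 20 (4.88 and 6.05). By nearest gene the housekeeping counts were 1 and 5 of 20 (1.81 and 2.14), so that of endogenous Sox2 fell below its random mean. Whether the counts of these lists differ between the libraries was not tested.

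**Figure D2:**
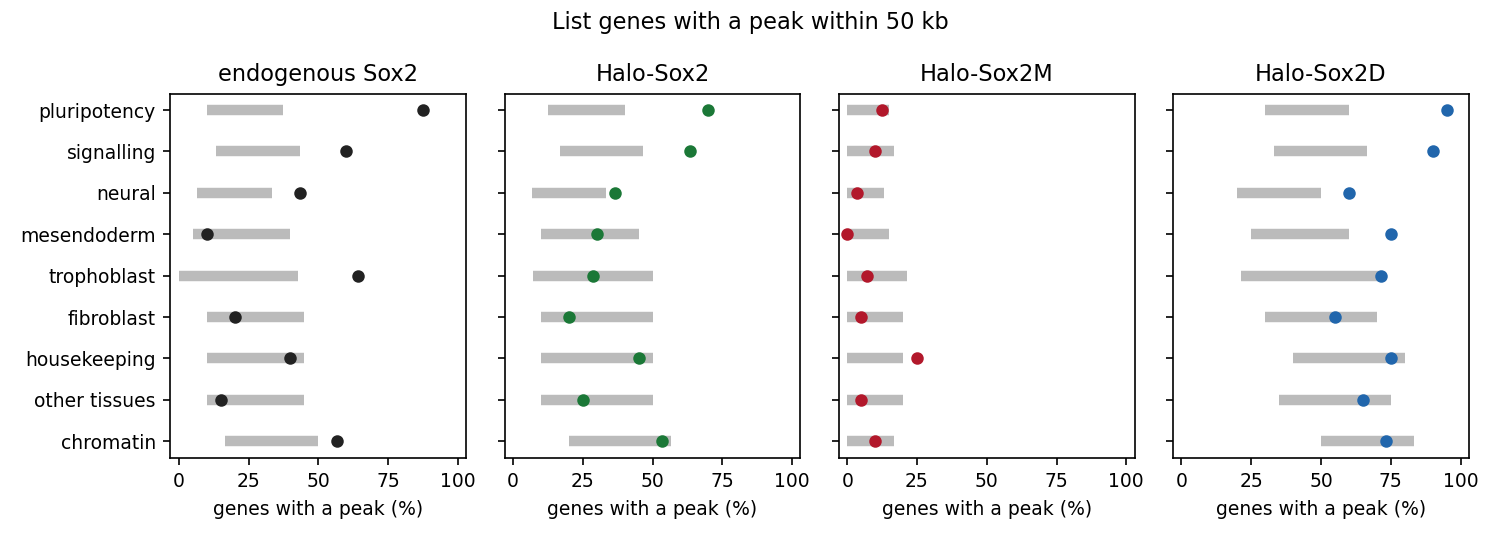
Share of the genes of each fixed list with a peak within 50 kb (points, % of list genes) in each of the 4 libraries, with grey bars for the central 95% of 10000 matched random lists. The pluripotency points lie above the bars for endogenous Sox2 (35 of 40 genes), Halo-Sox2 (28) and Halo-Sox2D (38), and inside the bar for Halo-Sox2M (5) at this window. As ratios to the random mean these counts were 3.79, 2.66, 2.10 and 2.16 in that order. Lying inside or above a bar thus depends on the length of the list too.

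Over the genome, 617 of the 7153 endogenous Sox2 peaks overlapped a Halo-Sox2 peak by at least 1 bp (8.63%, 7.997 to 9.30%), and 608 of the 6558 Halo-Sox2 peaks overlapped an endogenous one (9.27%, 8.59 to 9.997%). When one list was moved by 1 to 10 kb, a mean of 50.3 endogenous Sox2 peaks overlapped. With peaks this narrow the overlap depended on the criterion: 35.2% of endogenous Sox2 peaks (34.1 to 36.3%) had a Halo-Sox2 centre within 500 bp and 31.0% of Halo-Sox2 peaks (29.9 to 32.1%) had an endogenous one. Among the 2520 endogenous Sox2 peaks within 500 bp the median distance between centres was 32 bp. Part of the sharing came from 100-kb stretches with 15 or more peaks in a library, from mitochondrial DNA and from unplaced sequence. Outside these dense bins 29.8% of endogenous Sox2 peaks (28.7 to 30.9%) had a Halo-Sox2 centre within 500 bp, against 0.876% after the 1 to 10 kb moves.

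**Figure D3:**
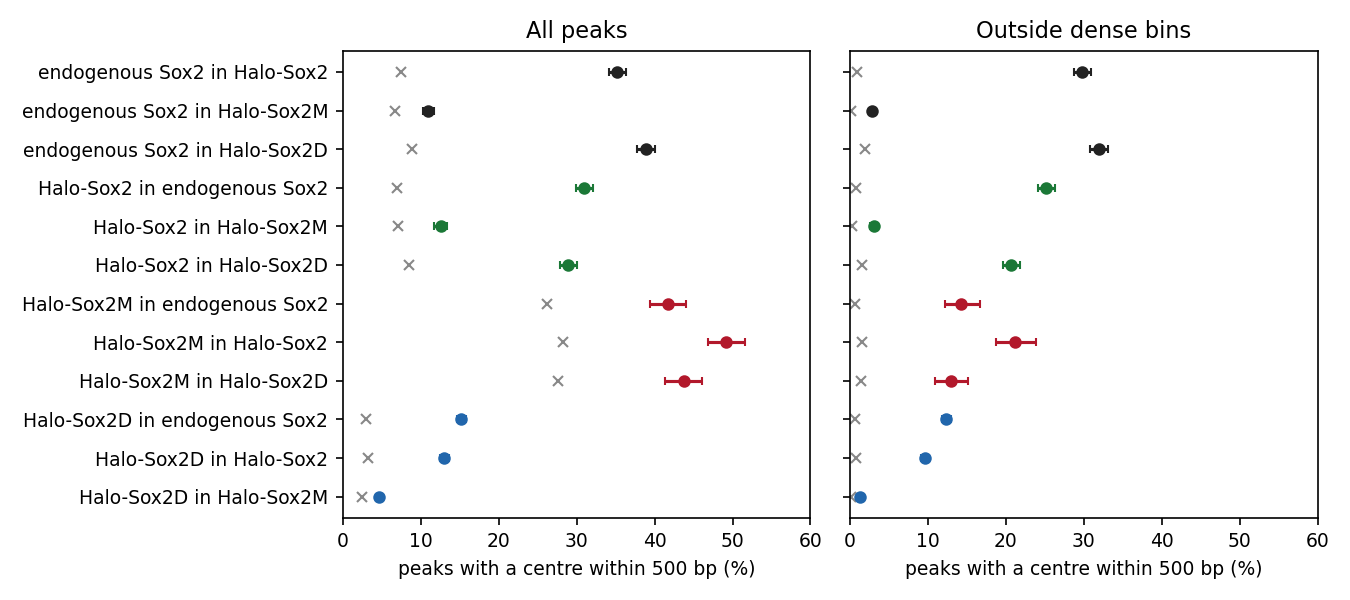
Share of the peaks of one library with a peak centre of another within 500 bp (points with 95% Wilson intervals, %), for all peaks (left) and outside dense bins (right), with crosses for the mean of 100 moves of the second list by 1 to 10 kb. For Halo-Sox2M in Halo-Sox2 the share is 49.2% over all peaks and 21.2% outside dense bins, above the crosses in both panels.

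The second comparison set Halo-Sox2M, with changes in the HMG box that binds DNA, against Halo-Sox2. Pou5f1, Nanog, Phc1 and Prdm14 (a regulator of naive pluripotency) had 3, 3, 4 and 4 Halo-Sox2 peaks and 0 Halo-Sox2M peaks. They were among 86 list genes with this pattern, as were Sox21 with 6 peaks, Etv5 and Jarid2 with 4, and Kdm3a and Neurog1 with 3. Lack of a Halo-Sox2M peak was the common state: of all 21887 protein-coding genes, 6.37% had one, against 32.3% with a Halo-Sox2 peak. The pattern is therefore not particular to these genes. Overlapping peaks of both libraries were found at 3 list genes: Fgfr2, an FGF receptor (3 Halo-Sox2 and 2 Halo-Sox2M peaks), Mtf2 (3 and 1) and Sdha (1 and 1). The Halo-Sox2 peaks concerned lay inside Fgfr2 (chromosome 7, 130264833 to 130264847), inside Mtf2 (chromosome 5, 108077191 to 108077206) and 49.2 kb above Sdha. Fn1, Kat5, Meis1 and Ppia had 1 Halo-Sox2M peak each and no Halo-Sox2 peak. Of the pluripotency list, 5 of 40 genes had a Halo-Sox2M peak (Sox2, Klf2, Tcf7l1, Rif1 and Foxd3, with 1 peak each, some of them named after their values were seen), against a random mean of 2.32, and 92.55% of random lists held fewer. That standing depended on the window, with 98.96% of random lists holding fewer at 20 kb, 97.43% by nearest gene and 85.74% at 100 kb.

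The Halo-Sox2 list was 3.83-fold longer than the Halo-Sox2M list, and 6.11-fold longer outside dense bins, where 954 Halo-Sox2M peaks remained. Dense bins, mitochondrial DNA and unplaced sequence held 44.2% of the Halo-Sox2M peaks (41.9 to 46.6%) against 11.1% of the Halo-Sox2 peaks (10.4 to 11.9%). When the Halo-Sox2 list outside dense bins was thinned at random to 954 peaks, a mean of 8.91 pluripotency genes had a peak (SD over 100 draws 2.43, range 3 to 17), so the 5 genes of Halo-Sox2M lay within the range that a Halo-Sox2 list of that length gave. Endogenous Sox2 lists of that length gave 7 to 24 genes. When the whole Halo-Sox2 list was thinned to 1711 peaks, the mean was 13.4 genes (range 5 to 20), so 5 genes equalled the lowest draw. Of the other lists, 5 of 20 housekeeping genes had a Halo-Sox2M peak (random mean 1.28), and 99.26% of random lists held fewer. The percent of random lists with fewer was 99.56% at 20 kb (4 of 20 genes) and 95.82% at 100 kb (5 of 20). By nearest gene it was 92.94% (2 of 20). Signalling and chromatin genes had 3 of 30 each (random means 1.84 and 2.10), neural genes 1 of 30 (1.39) and trophoblast genes 1 of 14 (0.822). Fibroblast genes and genes of other tissues had 1 of 20 each (1.22 and 1.25), and mesendoderm genes 0 of 20 (1.13). By overlap of at least 1 bp, 278 Halo-Sox2 peaks lay in the Halo-Sox2M list (4.24%, 3.78 to 4.75%) and 277 Halo-Sox2M peaks in the Halo-Sox2 list (16.2%, 14.5 to 18.0%). Outside dense bins these shares were 0.823% (0.622 to 1.09%) and 4.93% (3.72 to 6.49%). Within 500 bp and outside dense bins, 21.2% of Halo-Sox2M peaks (18.7 to 23.9%) had a Halo-Sox2 centre, against 1.52% after the 1 to 10 kb moves. The share fell to 11.1% without bins of 5 or more peaks and to 6.07% without bins of 3 or more.

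The third comparison set the truncated Halo-Sox2D, which keeps the HMG box and lacks the C-terminal activation region, against Halo-Sox2. Of the pluripotency list, 38 of 40 genes had a Halo-Sox2D peak (random mean 18.1), all but Zfp42 and Nr0b1. Signalling genes had 27 of 30 (random mean 14.9), and for both lists every random list held fewer. Overlapping peaks of both libraries lay at 9 list genes: Spry2 (11 Halo-Sox2 and 9 Halo-Sox2D peaks), Tcf7l1 (5 and 12), Jarid2, a Polycomb-associated factor (4 and 7), Pou5f1 (3 and 7), Phc1 (4 and 3), Stat3, the effector of LIF signalling (2 and 4), Neurog1 (3 and 1), Thy1 (1 and 3) and Hdac1 (1 and 2). The Halo-Sox2 peak concerned lay inside Jarid2 (chromosome 13, 44751951 to 44751964) and 0.122 kb above Stat3 (chromosome 11, 100939713 to 100939720).

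Many more list genes had Halo-Sox2D peaks without Halo-Sox2 peaks (84) than the reverse (17). Mbd3, a subunit of the NuRD complex, had 7 Halo-Sox2D peaks and 0 Halo-Sox2 peaks. Ppia and Rps18 had 6 Halo-Sox2D peaks, Polr2a, Smad7, Tfcp2l1, Tubb3, Wdr5 and Zfp281 had 5, and Bmpr1a had 4. In the other direction Tet2 had 3 Halo-Sox2 peaks, Acta2 had 2, and B2m, Chd7, Dcn, Eed, Foxa2, Lum and Nr0b1 had 1. The Halo-Sox2D counts for the remaining lists were 18 of 30 neural genes (random mean 10.3), 15 of 20 mesendoderm genes (8.47), 10 of 14 trophoblast genes (6.40) and 22 of 30 chromatin genes (20.2). They were 15 of 20 housekeeping genes (11.97), 11 of 20 fibroblast genes (9.76) and 13 of 20 genes of other tissues (11.2). For neural and mesendoderm genes 99.8 and 99.78% of random lists held fewer, and by nearest gene 100 and 90.31%. A high standing was thus not particular to pluripotency and signalling genes. The Halo-Sox2D list was 2.11 times as long as that of Halo-Sox2, and 57.7% of all 21887 protein-coding genes had a Halo-Sox2D peak against 32.3% for Halo-Sox2, 27.4% for endogenous Sox2 and 6.37% for Halo-Sox2M. When both lists outside dense bins were thinned to 954 peaks, a mean of 7.99 pluripotency genes (SD over draws 2.40) had a Halo-Sox2D peak, against 8.91 for Halo-Sox2. By overlap of at least 1 bp, 467 Halo-Sox2 peaks lay in the Halo-Sox2D list (7.12%, 6.52 to 7.77%), and 467 Halo-Sox2D peaks in the Halo-Sox2 list (3.38%, 3.09 to 3.69%). Outside dense bins, 20.7% of Halo-Sox2 peaks (19.7 to 21.8%) had a Halo-Sox2D centre within 500 bp, and 25.2% (24.1 to 26.3%) had an endogenous Sox2 centre. These lists differ in length, and when each was thinned to 954 peaks the shares were 2.11 and 6.28% (SD over draws 0.224 and 0.363). Thinning removed more of the 13241 Halo-Sox2D peaks than of the 6364 endogenous Sox2 peaks. The thinned shares therefore cannot decide which list held more of the Halo-Sox2 places.

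Halo-Sox2D peaks lay near the ends of protein-coding genes more often than peaks of the other libraries. Among peaks on the autosomes, X and Y (13523 for Halo-Sox2D, 1409 for Halo-Sox2M, 6195 for Halo-Sox2 and 6812 for endogenous Sox2), the share within 1 kb of either end was 21.3% for Halo-Sox2D (20.6 to 22.0%), 11.001% for Halo-Sox2M (9.47 to 12.7%), 10.2% for Halo-Sox2 (9.49 to 10.997%) and 6.34% for endogenous Sox2 (5.79 to 6.95%). Over these peaks the intervals of Halo-Sox2M and Halo-Sox2 overlapped. Positions drawn uniformly on the same chromosomes gave 3.09 to 3.17%. Outside dense bins the Halo-Sox2M share was 15.8% (13.6 to 18.3%). Of the peaks on these chromosomes, 51.1% lay inside protein-coding genes for Halo-Sox2D, 43.4% for Halo-Sox2, 40.7% for endogenous Sox2 and 24.4% for Halo-Sox2M. Uniformly drawn positions gave 40.4 to 40.8%. Outside dense bins the Halo-Sox2M share inside genes was 32.8% (29.9 to 35.9%). The gene table gives no strand, so starts and ends of transcription were not told apart.

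**Figure D4:**
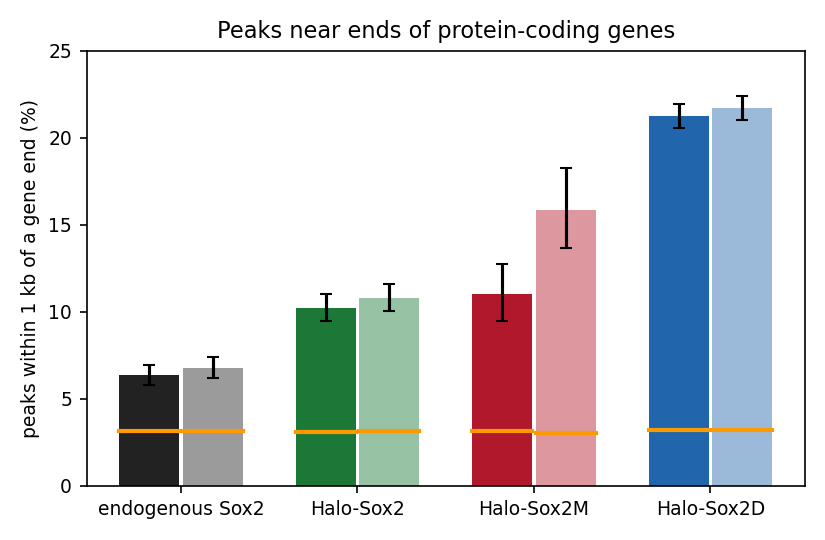
Share of peaks within 1 kb of either end of a protein-coding gene (bars, %, with 95% Wilson intervals) in each of the 4 libraries, for all peaks on the autosomes, X and Y (dark) and outside dense bins (pale), with orange lines for uniformly drawn positions. The dark Halo-Sox2D bar, at 21.3%, is the tallest and the endogenous Sox2 bar, at 6.34%, the lowest of the 4.

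When peaks of all 4 libraries outside dense bins were joined into sites wherever centres lay within 500 bp, 19364 sites resulted. Of these, 16906 held peaks of 1 library, 1970 of 2, 465 of 3 and 23 of all 4. Endogenous Sox2 and Halo-Sox2 shared 1080 sites, and 430 of them also held a Halo-Sox2D peak (39.8%, 36.9 to 42.8%), while 51 held a Halo-Sox2M peak (4.72%, 3.61 to 6.16%). A Halo-Sox2D list thinned at random to 954 peaks, as many as Halo-Sox2M had, reached 4.31% of the shared sites (SD over 100 draws 0.546). That fall follows from removing most Halo-Sox2D peaks at random, while the Halo-Sox2M list stayed whole. It cannot tell whether Halo-Sox2M held these sites as often as Halo-Sox2D. Of the 4066 Halo-Sox2 sites without endogenous Sox2, 12.4% (11.4 to 13.4%) held a Halo-Sox2D peak and 1.55% (1.21 to 1.98%) a Halo-Sox2M peak. Because sites were joined over all libraries, peaks of Halo-Sox2D or Halo-Sox2M could themselves link the other libraries' peaks into a shared site. Asking for peaks of both endogenous Sox2 and Halo-Sox2 may also pick wider, peak-rich sites. The contrast with the 4066 sites may therefore be partly built in.

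The protein-coding genes with most peaks in their windows over the whole genome were partly neighbours of repeated sequence. For endogenous Sox2 they were Sfi1 (25 peaks), Eif4enif1 and Gm51877 (22 each), which adjoin each other on chromosome 11, Spry2 (17) and Btbd9 (16). In the Halo-Sox2 list Gm40363 had 71 peaks, and Gm36327, Gm40364, Gm40365 and Gm40367 had 37 each, all in one cluster on chromosome 6. The Halo-Sox2M list was led by Gm40363 (90), by Gas8 on chromosome 8 beside the 5S rRNA genes (47), and by Gm36327, Gm40364 and Gm40365 (42 each). In the Halo-Sox2D list Arhgap26 had 25 peaks, Btbd9 and Gm40363 had 21, Dnah8 had 20 and Gm37013 had 18.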

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

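All tests in this part were chosen after the results were seen. The regions below are repeats, mitochondrial DNA, unplaced sequence and tRNA genes, which the main comparisons did not address by themselves although their peaks counted in the lists. With no control library, they are given because their peak numbers exceed the 3 that a count of 0 allows.

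The array of 5S rRNA genes on chromosome 8 (123500001 to 123700000) held 101 Halo-Sox2M peaks, which is 5.90% of that list (4.88 to 7.12%), against 2 peaks in each of the other 3 lists. The ratio of Halo-Sox2M to Halo-Sox2 peaks was 0.153 (0.0825 to 0.265) on mitochondrial DNA, against 50.5 (13.6 to 423) in the 5S array. Peak numbers were thus not raised alike in multi-copy sequence of every kind. A larger intake of such sequence cannot be judged from this, because mitochondrial DNA left in the nuclei used may differ between libraries. A rise confined to nuclear repeats stays open: the ratio was 1.27 (0.918 to 1.76) in the Rn4.5s array and 1.07 (0.949 to 1.22) in 4 further regions, but peak numbers may be saturated there, and as shares of the list these regions were higher in Halo-Sox2M (5.26 against 1.08% in the Rn4.5s array, 12.9 against 3.03% in the bin of Mir101c). One fixed set of resin background peaks at RNA polymerase III genes cannot be told apart from other sources, because the 27 tRNA genes with a Halo-Sox2M peak are too few: 11.1% of them (3.85 to 28.1%) also had a Halo-Sox2 peak, against 9.80% of all tRNA genes. The treatment of reads that map to many 5S copies and a difference due to the changed residues of Halo-Sox2M stay open as well, untested with 1 library per group.

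The other regions are given as values. The array around Rn4.5s on chromosome 6 (47600001 to 47800000) held 90 Halo-Sox2M, 71 Halo-Sox2, 22 Halo-Sox2D and 9 endogenous Sox2 peaks. The first 100 kb listed on chromosome 9 (3000001 to 3100000) held 249 endogenous Sox2, 220 Halo-Sox2M, 199 Halo-Sox2 and 162 Halo-Sox2D peaks. On chromosome 2 (98600001 to 98700000) there were 29 Halo-Sox2, 24 Halo-Sox2M, 20 Halo-Sox2D and 15 endogenous Sox2 peaks. On chromosome 14 (19400001 to 19500000) there were 25 Halo-Sox2D, 24 Halo-Sox2, 22 endogenous Sox2 and 18 Halo-Sox2M peaks. The bin of AY036118 and Rn18s-rs5 on chromosome 17 (39800001 to 39900000), which carries ribosomal RNA sequence, held 124 endogenous Sox2 and 23 Halo-Sox2D peaks and 0 of Halo-Sox2 and Halo-Sox2M. One unplaced sequence held 317 endogenous Sox2, 274 Halo-Sox2M, 247 Halo-Sox2 and 201 Halo-Sox2D peaks. Mitochondrial DNA held 98 Halo-Sox2, 90 Halo-Sox2D, 15 Halo-Sox2M and 3 endogenous Sox2 peaks. Within 100 bp of the 408 annotated tRNA genes lay 59 Halo-Sox2D, 42 Halo-Sox2, 27 Halo-Sox2M and 21 endogenous Sox2 peaks. As shares of each list these are 0.427% for Halo-Sox2D, 0.640% for Halo-Sox2, 1.58% for Halo-Sox2M and 0.294% for endogenous Sox2. Of the 27 tRNA genes with a Halo-Sox2M peak, 3 also had a Halo-Sox2 peak, against 2.65 for independent lists.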

How the results depend on the processing

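No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The stricter peak threshold and the motif alternatives were not run, for want of scores and of sequence. The alternatives outside dense bins were chosen after the data were seen. Depth limits every comparison of list lengths, since neither reads nor scores were used here. A share was called moved when it left the main interval, and a count when it changed more than 1.5 times. Among the results that answer a comparison, 33 values under alternatives stayed close to the main value and 61 moved. The pluripotency counts stayed within 1.5 times under gene windows of 20 and 100 kb, the nearest gene and outside dense bins in the 4 libraries, but the Halo-Sox2M count of 5 exceeded the upper end of the central 95% of random lists, 4, at 20 kb and lay within it in the other windows. Peak numbers did so too, except that 954 Halo-Sox2M peaks remained outside dense bins. For single lists other than pluripotency, 111 counts stayed within 1.5 times and 81 moved: 48 became lower by thinning, 10 lower at 20 kb, 9 higher at 100 kb, and 13 lower and 1 higher by nearest gene.

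Sharing followed the criterion by construction. The shares are given in the order endogenous Sox2 in Halo-Sox2, Halo-Sox2 in endogenous Sox2, Halo-Sox2 in Halo-Sox2M, Halo-Sox2M in Halo-Sox2, Halo-Sox2 in Halo-Sox2D and Halo-Sox2D in Halo-Sox2. They were 4.31, 4.71, 2.10, 8.01, 3.49 and 1.65% with 50% of both peaks overlapping. They were 22.0, 21.3, 7.90, 31.9, 15.5 and 7.34% with centres within 50 bp, and 35.2, 31.0, 12.5, 49.2, 29.0 and 13.0% within 500 bp. On autosomes and X they were 7.52, 8.17, 2.80, 12.1, 5.82 and 2.65%. Outside dense bins they were 6.35, 6.83, 0.823, 4.93, 4.67 and 2.04% by overlap and 29.8, 25.2, 3.04, 21.2, 20.7 and 9.61% within 500 bp. With lists thinned to 1711 peaks they were 2.24, 2.23, 4.20, 4.24, 0.876 and 0.874%. The order of Halo-Sox2M and Halo-Sox2D turned, but the Halo-Sox2M list stayed whole while Halo-Sox2D lost most peaks at random. Without scores it cannot be told whether a Halo-Sox2D list called at that length would share as little. For thinned lists within 500 bp the shares of Halo-Sox2 in Halo-Sox2M and in Halo-Sox2D were 12.5 and 7.38%. Outside dense bins, thinned to 954 peaks, they were 0.844 and 0.336% by overlap (SD over draws 0.287 and 0.189) and 3.02 and 2.02% within 500 bp (0.576 and 0.481).

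In the order endogenous Sox2, Halo-Sox2, Halo-Sox2M and Halo-Sox2D, the share of peaks on the autosomes, X and Y near a gene end was 11.04, 15.4, 16.3 and 27.1% within 2 kb, 21.1, 25.5, 24.1 and 37.6% within 5 kb, and 12.9, 16.6, 26.1 and 27.9% for all annotated genes. Halo-Sox2D had the highest share under these settings, and its interval of 27.2 to 28.7% for all annotated genes overlapped that of Halo-Sox2M, 23.9 to 28.5%. Outside dense bins the Halo-Sox2M and Halo-Sox2 shares were 15.8 and 10.8%. There and for all annotated genes the intervals of Halo-Sox2M and Halo-Sox2 did not overlap. Thinning to 1711 peaks left 21.2, 13.4 and 12.8 pluripotency genes with a peak for endogenous Sox2, Halo-Sox2 and Halo-Sox2D, and thinning to 954 outside dense bins left 16.1, 8.91 and 7.99, against 5 for Halo-Sox2M. The fall from the main counts follows from the shorter lists, and Halo-Sox2D no longer had the highest count. The lowest draws were 14, 5 and 6 at 1711 peaks and 7, 3 and 2 at 954 peaks. At 1711 peaks the 5 of Halo-Sox2M equalled the lowest Halo-Sox2 draw and lay below all endogenous Sox2 and Halo-Sox2D draws. At 954 peaks it lay below all endogenous Sox2 draws and inside the range of the Halo-Sox2 and Halo-Sox2D draws. The cause was not tested.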

Other observations

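All tests in this part were chosen after the results were seen. Endogenous Sox2 peaks came in clusters more often than those of the tagged proteins. Outside dense bins, 26.0% of its 4503 sites (24.8 to 27.3%) held more than 1 peak, against 10.4% for Halo-Sox2 (9.62 to 11.3%), 9.54% for Halo-Sox2D (9.02 to 10.1%) and 5.47% for Halo-Sox2M (4.13 to 7.22%). Among genes chosen after their values were seen, Jarid2 had 15 endogenous Sox2 peaks, Klf5 and Mycn had 9, and these genes had 4, 2 and 2 Halo-Sox2 peaks. Outside dense bins the genes with most endogenous Sox2 peaks after Spry2 and Btbd9 were Pakap (16), Jarid2 (15) and Ppp1r9a (14). Those with most Halo-Sox2 peaks were Zfp978 and Zfp993 (19 each), of a zinc finger gene cluster on chromosome 4.

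Halo-Sox2M peaks lay within 500 bp of Halo-Sox2 peaks in 21.2% of cases outside dense bins. Bins with many peaks as the sole source are argued against. Without any bin of 5 or more peaks the share was 11.1% (8.98 to 13.6%), against at most 2.38% after moves of 1 to 10 kb. Without bins of 3 or more it was 6.07% (4.35 to 8.40%). Multi-copy sequence with fewer peaks per bin stayed in, so as a source it cannot be told apart from others. Resin background as the sole source cannot be told apart from other sources. Of the 114 Halo-Sox2 sites with a Halo-Sox2M peak, 44.7% (35.9 to 53.9%) also held an endogenous Sox2 peak from the antibody library. Among the other Halo-Sox2 sites it was 20.4% (19.36 to 21.6%). Sites were joined over all libraries, so asking for peaks of both tagged libraries may pick wider, peak-rich sites whatever the source. Background common to antibody and resin, such as open chromatin, cannot be told apart from binding, since no input library was used here. This holds for the 51 of these 114 sites with an endogenous Sox2 peak, which include the 23 sites of all 4 libraries. Residual binding by Halo-Sox2M, or endogenous Sox2 carried along with it, may equally be the source and was not tested.

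Halo-Sox2D peaks lay near gene ends in 21.7% of cases outside dense bins (21.01 to 22.4%). Halo-Sox2D peaks with no endogenous Sox2 peak within 500 bp lay near gene ends in 23.3% of cases (22.6 to 24.1%). The share was 16.9% (14.5 to 19.6%) of such Halo-Sox2M peaks and 12.4% (11.5 to 13.5%) of such Halo-Sox2 peaks. Such peaks make up most of each list (11605 of 13241 for Halo-Sox2D), so these values nearly repeat the shares of the whole lists. They cannot decide whether a larger number of the same peaks that endogenous Sox2 lacks was the source. Fuller detection of sites common to endogenous Sox2 and Halo-Sox2 cannot be told apart from other sources: the 649 Halo-Sox2D peaks near peaks of both lay near gene ends in 8.47% of cases (6.57 to 10.9%), but their choice largely sets that value and sites those lists missed are not seen. More reads or a looser threshold in a list 2.11 times as long as that of Halo-Sox2 cannot be told apart from a change in binding, since no reads or scores were used here. A difference due to the truncation is a hypothesis that 1 library per group left untested.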
